A study of Mus musculus with 30 samples.

How the data were processed

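Gene expression was measured on 2-colour arrays in peripheral blood leukocytes of DBA/2 mice that were untreated or had received 83 mg per kg cyclophosphamide by intraperitoneal injection 1, 2 or 5 days earlier. Per the labels' protocols, amplified RNA of each blood sample was labelled with Cy5, and a reference of pooled bone marrow cells was labelled with Cy3 on every array. The cell type label calls that pool untreated, while a treatment label of the reference channel names cyclophosphamide at 83 mg per kg. The reference is assumed here to be 1 pool used throughout, and values are only compared between groups of blood samples, so that a constant reference drops out. Cy5 marks the blood sample in every column, so a dye effect is part of every ratio and also drops out of differences between groups.

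The deposited values are log ratios, 1 per probe and column, per the labels' dyes Cy5 and Cy3. The scanner, background correction, normalization and filter behind them are not given in the sources used here. The base of the logarithm is not given either. The values run from -4.70 to 5.76, beyond the 4.82 that log10 of the highest 16-bit intensity would allow, and the deposited values, made by the authors by steps not given here, were taken as log2 ratios of Cy5 over Cy3; base e is not excluded, in which case every printed log2 value would be a natural logarithm. The direction was taken as blood over marrow from the dyes. In untreated samples the median log2 ratio was 2.15 over the platelet list and 0.93 over the T cell list, against -1.18 over the cell division list and -0.90 over the DNA replication list. Column medians lay between -0.0028 and 0.025, so the deposited columns are centred near 0 and the ratios show unequal change, not absolute amounts.

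Between 5314 and 9398 of the 13443 probes had a value in a column (39.5% to 69.9%), and why the others are empty is not given in the sources used here. The 30 columns were 15 blood samples with 2 technical replicates each: 4 untreated samples, 4 at day 1, 4 at day 2 and 3 at day 5, independently harvested per the labels. Technical replicates correlated with r between 0.829 and 0.957 across probes, and 0 values were identical within a pair. The series design speaks of replicates within an array, so a pair may come from 1 array or from separate ones. Columns of different samples of a group had a median r of 0.757, and columns of different groups 0.649. Technical replicates were averaged and counted as 1 sample. The number of arrays, which carry 15 independent samples, limits the precision of every value.

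Probes were named through the platform annotation. There were 10032 probes with 1 gene symbol, 170 with several and 3241 with none; probes with several symbols or none were kept under their probe number and are not named. The 9616 symbols were checked against current ones through their gene identifiers: 0 changed, and 4 were kept as given because the gene table did not hold them. The 389 symbols with more than 1 probe were averaged over their probes, which gave 13027 features. Features with a value in at least 3 of 4 samples of the untreated, day 1 and day 2 groups and in at least 2 of 3 day 5 samples were tested, 6515 in all, 4725 of them with a symbol and 4920 with values in all 15 samples. Cd3e, Cd79a, S100a8, Mki67 and Kit are on the array but had too few values to be tested. No genome build is given for the probes, so no coordinates are printed.

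Tests used limma 3.58.1 in R 4.3.3 with 1 mean per group over all 15 samples, lmFit and eBayes, and Benjamini-Hochberg adjustment over the tested features within each comparison. A feature was called at an adjusted p under 0.05. A moderated F test asked whether a feature differed between any of the 4 groups. A log2 change is always the first-named group minus the second, given with its standard error (SE) from the fit, and a group mean with its standard deviation (SD) over samples. On simulated data drawn with the measured spreads, with 200 features changed, the procedure recovered 36.6%, 87.2% and 99.1% of changes of 0.5, 1 and 2 log2 units for day 1 against untreated, 35.1%, 84.2% and 98.9% for day 2, and 29.0%, 83.9% and 99.1% for day 5, each over 6515 features. False calls made up 5.48%, 4.54% and 4.15% of the calls. The simulations drew features independently and, like the fit, used 1 spread per feature for all 4 groups. The measured groups were not equally alike, with a median correlation between samples of 0.914 within day 1 and 0.801 within day 5. These rates therefore hold only for the simulated setting.

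The 27 gene lists were fixed before the data were examined: B cell, T cell, natural killer (NK) and cytotoxic cell, monocyte, mature neutrophil, neutrophil precursor granule, erythroid, platelet and megakaryocyte, stem and progenitor cell, cell division, DNA replication, p53 target, DNA repair and damage signalling, aldehyde and glutathione detoxification, interferon-stimulated, cytokine and chemokine, regulatory T cell, MHC class II, dendritic cell, a joint list of eosinophils, basophils and mast cells, adhesion and homing, apoptosis, unfolded protein response and heat shock, immediate early, endothelial and fibroblast, ribosomal protein, and oxidative phosphorylation. Of 912 genes in these lists, 830 were on the array and 387 were tested. Lists were compared with all other tested features by limma's cameraPR on the moderated t, two-sided, with a preset correlation between genes of 0.01 and adjustment over the 27 lists. The same test with a correlation estimated from the residuals, and limma's fry on the genes complete in all samples, were alternatives. Counts of called members are given over all tested features and adjusted over the list alone. Means of a list per sample use its genes with values in all 15 samples.

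The text names, for each day against untreated, the 6 largest rises and the 6 largest falls among called genes with a full gene symbol whose treated samples all lay beyond all untreated samples; for each comparison between days, 4 and 4 by the same rule; and, among the 4 members of each list with the smallest moderated F p, mainly those that passed the test, together with Cdkn1a, Hba-a1 and Pf4. This rule, the lists and the main tests were written before the data were examined. Alternatives were median centring or quantile normalization of the columns, a stricter filter and none, single probes, each technical replicate alone, all 30 columns with the sample as a random effect, a robust trended prior, array weights, fits of 2 groups alone, the replicate number as a block, a 2-fold minimum and each sample left out in turn. After seeing the data, 2 more were added: leaving out the 2 samples whose technical replicates were least alike, and leaving out the features that moved with Alas2. The correlation of day 1 and day 2 changes, and after seeing the data that of day 2 and day 5, was set against 100 simulations of unchanged groups, and the overlap of calls against fits in which each day had its own 2 untreated samples.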

Results

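The series asks how gene expression in circulating leukocytes changes after cyclophosphamide, an alkylating cytotoxic drug that is toxic to dividing blood cell precursors. Peripheral blood leukocytes of DBA/2 mice, an inbred strain, comprised 4 untreated samples and 4 at day 1, 4 at day 2 and 3 at day 5 after 83 mg per kg, each measured in 2 technical replicates. The values are log2 ratios of blood leukocytes over a bone marrow reference. The median correlation between samples across features was 0.818 within the untreated group, 0.914 within day 1, 0.812 within day 2 and 0.801 within day 5. Between untreated and day 2 samples it was 0.601, and between day 2 and day 5 samples 0.446. Of 6515 tested features, 1476 differed between any of the 4 groups in the moderated F test.

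One day after the drug, several platelet transcripts were higher and a few monocyte transcripts lower in blood leukocytes. Treml1 (gene 71326), a receptor of platelet granules, rose by a log2 change of 1.96 ± 0.39 (SE, limma adjusted p = 0.016), from 1.66 ± 0.41 (SD, n = 4) in untreated to 3.61 ± 0.17 (SD, n = 4) samples. Itga2b, the platelet fibrinogen receptor chain, rose by 1.37, F2rl2, a protease-activated receptor, by 1.33, and Clu, which encodes clusterin, by 1.70 (adjusted p = 0.013, 0.025 and 0.022). Cd177, a neutrophil surface protein, fell by 1.25 ± 0.22 (SE, adjusted p = 0.0095), and Mpeg1, the macrophage perforin, fell by 0.85 (adjusted p = 0.012). In all, 300 features changed at day 1, 149 higher and 151 lower.

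Among the other largest rises at day 1 were Pcp4l1 (2.16, adjusted p = 0.037), Ereg, the growth factor epiregulin (1.96, adjusted p = 0.021), Serpinb6a, a serine protease inhibitor (1.73, adjusted p = 0.021), and Ipo11, a nuclear import receptor (1.72, adjusted p = 0.0098). The other largest falls were in Myf6 (-1.25, adjusted p = 0.020), a muscle transcription factor, Ttc8 (-1.22, adjusted p = 0.013), Serpina1a (-1.19, adjusted p = 0.037), a liver antiprotease, Syt9 (-1.18, adjusted p = 0.032), a synaptotagmin, and Sec61g (-1.17 ± 0.20, SE, adjusted p = 0.0095), a subunit of the endoplasmic reticulum channel. These 5 features, Myf6, Ttc8, Serpina1a, Syt9 and Sec61g, belong to a set of 102 features that moved together with Alas2, and 55 of the set were called at day 1.

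The platelet and megakaryocyte list rose at day 1: 4 of its 8 tested members passed the test, 7 when adjusted over the list alone, all 8 had positive changes, and the mean change was 1.20 (adjusted p = 4.95e-06). The adjusted p was 0.060 with an estimated correlation. Pf4, platelet factor 4, had a change of 1.71 that did not pass (adjusted p = 0.12). The monocyte list fell, with 3 of 13 members lower, 5 when adjusted over the list alone, and a mean of -0.24 (adjusted p = 0.0058). With an estimated correlation the list had an adjusted p = 0.33. Its members Mpeg1 and Adgre1, the F4/80 antigen (-0.67, adjusted p = 0.043), were among the falls. The stem and progenitor cell list rose, with 2 of 8 members higher, 5 adjusted over the list alone, and a mean of 0.47 (adjusted p = 0.018). An estimated correlation gave the list an adjusted p = 0.19. Adgrg1, an adhesion receptor, rose by 0.99 (adjusted p = 0.012), and Meis1, a homeobox factor of stem cells, by 0.64 (adjusted p = 0.041).

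The B cell list fell at day 1, with 2 of 11 members lower, also 2 adjusted over the list alone, and a mean of -0.29 (adjusted p = 0.026). The list had an adjusted p = 0.19 with an estimated correlation. Fcmr, the receptor for IgM, fell by 0.75 (adjusted p = 0.018). The eosinophil, basophil and mast cell list fell, with 0 of 8 members called over all features, 2 lower adjusted over the list alone, and a mean of -0.27 (adjusted p = 0.033). With an estimated correlation the list had an adjusted p = 0.16. Members of lists that were not called also changed: Dut, the enzyme that removes dUTP, rose by 1.13 ± 0.18 (SE, adjusted p = 0.0051), and the glutathione peroxidase Gpx4 by 1.06 (adjusted p = 0.012). Mgst1, a microsomal glutathione transferase, fell by 1.07 ± 0.15 (SE, adjusted p = 0.0051) and Gpx1 by 0.81 (adjusted p = 0.029). Itgb1, an integrin chain, rose by 0.95, the endothelial genes Kdr and Plvap by 0.97 and 0.88, and Tbx21, a T-helper and NK transcription factor, by 0.42 (adjusted p = 0.037, 0.033, 0.042 and 0.044). Izumo1r, the folate receptor 4 of regulatory T cells, fell by 0.74 (adjusted p = 0.047), and Ccr9, a homing receptor, by 0.54 (adjusted p = 0.041). Alas2, the erythroid enzyme of heme synthesis, had a change of -1.40 (adjusted p = 0.058), and Cdkn1a, a p53 target, one of -0.84 (adjusted p = 0.17). Gpx1 and Izumo1r are members of the set that moved with Alas2.

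The day 1 count depended on single samples: without replicate 1, 2 or 4 of day 1, 62, 60 and 62 features were called, and without untreated replicate 1, 2, 3 or 4, 195, 164, 80 and 72. Of 29 named calls at day 1, 7 were kept in every alternative (Ipo11, Sec61g, Adgrg1, Mpeg1, Mgst1, Gpx4 and Dut). Quantile normalization of the columns gave 462 calls, 182 higher and 280 lower. It ended the platelet list's call (mean 0.54, adjusted p = 0.073) and lowered the changes of Clu to 0.27, Itga2b to 0.58, Itgb1 to 0.48, Treml1 to 1.22 and Pcp4l1 to 1.38, none of which then passed (adjusted p = 0.64, 0.22, 0.28, 0.061 and 0.12). Clu also lost its call with a robust trended prior, with the replicate block and without untreated replicate 4 or day 1 replicate 1 or 2. Without day 1 replicate 2, Itga2b and Treml1 lost theirs too. The B cell list lost its call without untreated replicate 3 or day 1 replicate 3 (adjusted p = 0.060 and 0.078), and the eosinophil, basophil and mast cell list without untreated replicate 3 or day 1 replicate 1 or 2 (adjusted p = 0.077, 0.060 and 0.066). With no filter on missing values the stem and progenitor cell list had a mean of 0.21 and lost its call (adjusted p = 0.26), as did the B cell list (mean -0.19, adjusted p = 0.089). The B cell and the eosinophil, basophil and mast cell lists also lost theirs on complete genes (adjusted p = 0.21 and 0.061), with technical replicate 1 alone (0.10 for both) and in fits of 2 groups (0.061 and 0.068). Technical replicate 2 alone ended the calls of the monocyte list (adjusted p = 0.064) and the eosinophil, basophil and mast cell list (0.051), and the sample as a random effect ended that of the latter (0.074). The monocyte mean was -0.42 on complete genes and -0.45 with technical replicate 1 alone.

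At day 2 several transcripts of mature neutrophils (6 of 12 tested list members) were higher and several of monocytes (7 of 13) lower in blood leukocytes. The call of the neutrophil list held with an estimated correlation and that of the monocyte list did not (adjusted p = 0.0050 and 0.12). Csf3r, the G-CSF receptor, rose by 1.56 ± 0.21 (SE, adjusted p = 1.74e-04), from 0.45 ± 0.27 (SD, n = 4) to 2.02 ± 0.49 (SD, n = 4) in samples of day 2. S100a9, a calcium-binding protein abundant in neutrophils, rose by 1.71 (adjusted p = 0.0064), and the neutrophil receptors Trem1 and Fpr2 by 1.51 and 1.13 (adjusted p = 0.0019 and 0.0014). Ms4a6c, a membrane protein of monocytes, fell by 1.73 ± 0.18 (SE, adjusted p = 4.07e-05). A total of 826 features changed, 315 higher and 511 lower.

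**Figure D1:**
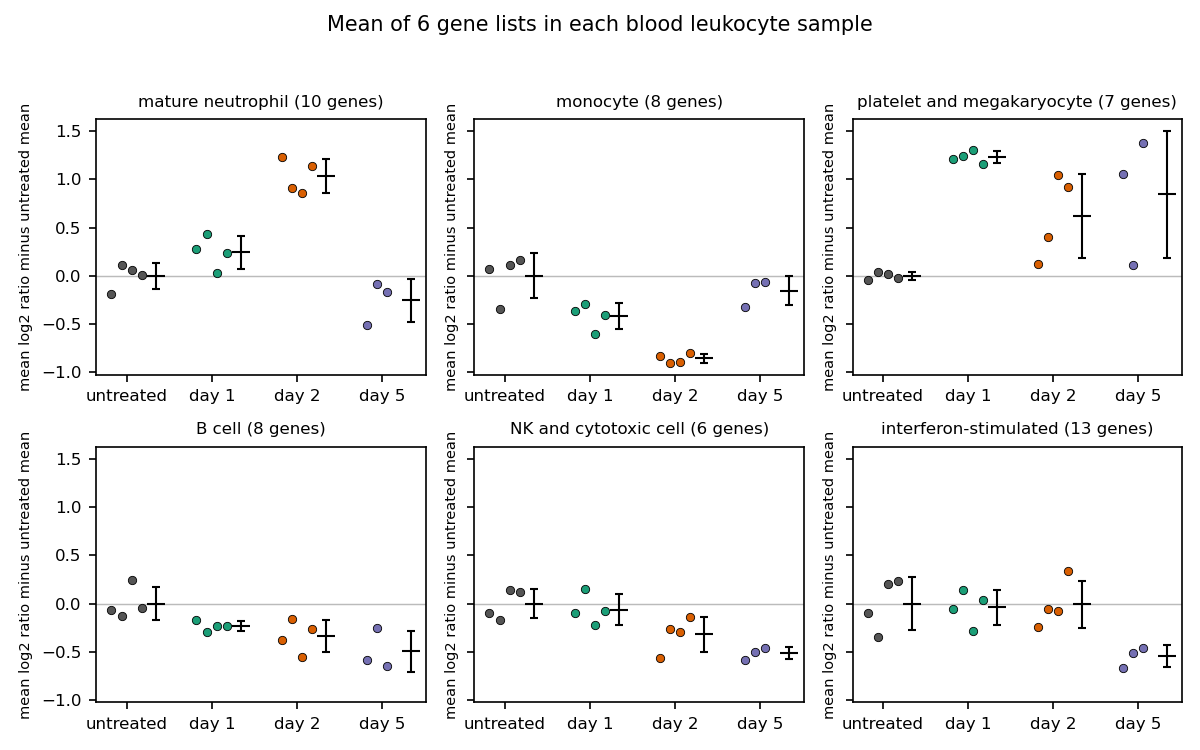
Mean log2 change of 6 gene lists in each sample relative to the untreated mean; the vertical axis is log2, points are samples, and bars show mean and SD per group. The mature neutrophil mean at day 2 was 1.04 ± 0.18, against a monocyte mean of -0.86 ± 0.047, and the platelet mean at day 1 was 1.23 ± 0.061.

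The mature neutrophil list rose at day 2, with 6 of 12 members higher, 7 adjusted over the list alone, all 12 positive, and a mean of 0.92 (adjusted p = 1.86e-05). This was the only list of any day against untreated that was called with both correlations (adjusted p = 0.0050 with an estimated correlation). The monocyte list fell, with 7 of 13 members lower, also 7 adjusted over the list alone, and a mean of -0.50 (adjusted p = 1.86e-05). An estimated correlation gave the list an adjusted p = 0.12. Its members Adgre1, Mpeg1 and F13a1, a coagulation factor chain, fell by 1.20, 1.05 and 0.85 (adjusted p = 3.02e-04, 3.96e-04 and 0.0079). The NK and cytotoxic cell list fell, with 4 of 9 members lower, 4 adjusted over the list alone, and a mean of -0.42 (adjusted p = 0.030). The list had an adjusted p = 0.63 with an estimated correlation. Nkg7, a granule protein, fell by 0.69 ± 0.13 (SE, adjusted p = 0.0028), Klrd1, the CD94 receptor, by 0.57 (adjusted p = 0.049), and Gzmk, a granzyme, by 0.84 (adjusted p = 0.045), with values in 3 day 2 samples. The eosinophil, basophil and mast cell list fell, with 3 of 8 members lower, 4 adjusted over the list alone, and a mean of -0.34 (adjusted p = 0.030). With an estimated correlation the list had an adjusted p = 0.12. Its mast cell tryptase Tpsb2 fell by 0.82, the basophil receptor Cd200r3 by 0.65 and the cytokine Il4 by 0.57 (adjusted p = 0.0010, 5.01e-04 and 0.044).

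The largest rises at day 2 were in Slc40a1, the iron exporter ferroportin (2.07 ± 0.21, SE, adjusted p = 3.77e-05), Grina (1.77, adjusted p = 5.36e-05), Myo7b, an unconventional myosin (1.77, adjusted p = 1.69e-04), S100a9, Csf3r and Chil1, a chitinase-like protein (1.56, adjusted p = 1.19e-04). The largest falls were in Syt9 (-2.87 ± 0.28, SE, adjusted p = 3.77e-05), Alas2 (-2.83 ± 0.40, SE, adjusted p = 2.43e-04), Myf6 (-2.64, adjusted p = 3.77e-05), Serpina1a (-2.63, adjusted p = 6.30e-05), Vav2, a guanine nucleotide exchange factor (-2.52, adjusted p = 2.85e-04), and Anxa4, an annexin (-2.49, adjusted p = 8.14e-05). All 6 of these falls belong to the set of 102 features that moved with Alas2, defined after the data were seen by a fall of at least 1 at day 2 and a rise of at least 1.5 from day 2 to day 5. The set's median change was -0.84 at day 1, -1.49 at day 2 and 0.43 at day 5.

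Among other members of lists, Il1rn, the interleukin 1 receptor antagonist, rose by 1.32, Txn1, thioredoxin, by 1.00, the interferon-induced Gbp2 by 1.22, Irf9 by 0.55, and Rgs2, a regulator of G protein signalling, by 0.93 (adjusted p = 0.0025, 3.38e-04, 0.0014, 0.036 and 6.61e-05). Ccl2, a monocyte chemoattractant, fell by 2.03, Ctsc, a lysosomal protease that activates granule proteases, by 2.07, Gpx1 by 1.27 and Plac8 by 1.03 (adjusted p = 0.0022, 5.35e-04, 3.15e-04 and 0.014). Cd4 rose by 0.53 (adjusted p = 0.042). Fcmr and Cd72, another B cell surface protein, fell by 0.69 and 1.38 (adjusted p = 0.0086 and 0.021). Bnip3l, a mitophagy receptor of maturing red cells, fell by 0.60 and Tnfrsf10b, a death receptor and p53 target, by 1.37, and Ddit4 fell by 1.13 (adjusted p = 0.0051, 2.49e-04 and 0.028). Izumo1r fell by 1.39, Ccr9 by 1.06, Batf3, a dendritic cell factor, by 1.07, Flt1, a VEGF receptor, by 1.13 and Pdia4, a protein disulfide isomerase, by 1.69 (adjusted p = 2.62e-04, 1.40e-04, 0.0049, 1.85e-04 and 0.0024). Of the cell division list, Smc4 and Cks2 rose by 0.51 and 0.78 and Nusap1 fell by 1.23 (adjusted p = 0.0086, 0.0088 and 0.033). Ccl2, Ctsc, Gpx1, Cd72, Tnfrsf10b, Izumo1r, Flt1, Pdia4 and Nusap1 are members of the set that moved with Alas2. Cdkn1a had a change of -0.95 (adjusted p = 0.085), and Hba-a1, an alpha globin gene, one of -0.32 (adjusted p = 0.12).

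Of 47 named calls at day 2, 38 were kept in every alternative; Klrd1, Gzmk, Il4, Irf9, Cd4, Cd72, Ddit4 and Nusap1 were lost without at least 1 sample, and Plac8 with the second technical replicate alone. Without the set that moved with Alas2, an alternative added after seeing the data, 669 features were called at day 2, and without untreated replicate 4, 529. The NK and cytotoxic cell list lost its call without untreated replicate 3 or 4, day 2 replicate 1 or day 5 replicate 3 (adjusted p = 0.060, 0.11, 0.079 and 0.053), and the eosinophil, basophil and mast cell list without untreated replicate 3 or day 2 replicate 3 (adjusted p = 0.060 and 0.063). Both lists also lost their call with technical replicate 2 alone (adjusted p = 0.14 and 0.093) and with the sample as a random effect (0.057 and 0.062). The NK and cytotoxic cell list lost it on complete genes, with array weights and in fits of 2 groups (adjusted p = 0.17, 0.072 and 0.080), and the eosinophil, basophil and mast cell list with no filter (mean -0.21, adjusted p = 0.096). Without untreated replicate 4 the NK and cytotoxic cell mean was -0.27. The monocyte mean was -0.86 on complete genes and -0.80 with technical replicate 1 alone. Quantile normalization gave changes of -0.89 for Klrd1, 0.75 for Gbp2 and 0.52 for Rgs2, which still passed. Il4 changed by -0.37 with technical replicate 1 alone, and Gzmk by -0.53 without the 2 least alike samples (adjusted p = 0.26 for both).

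**Figure D2:**
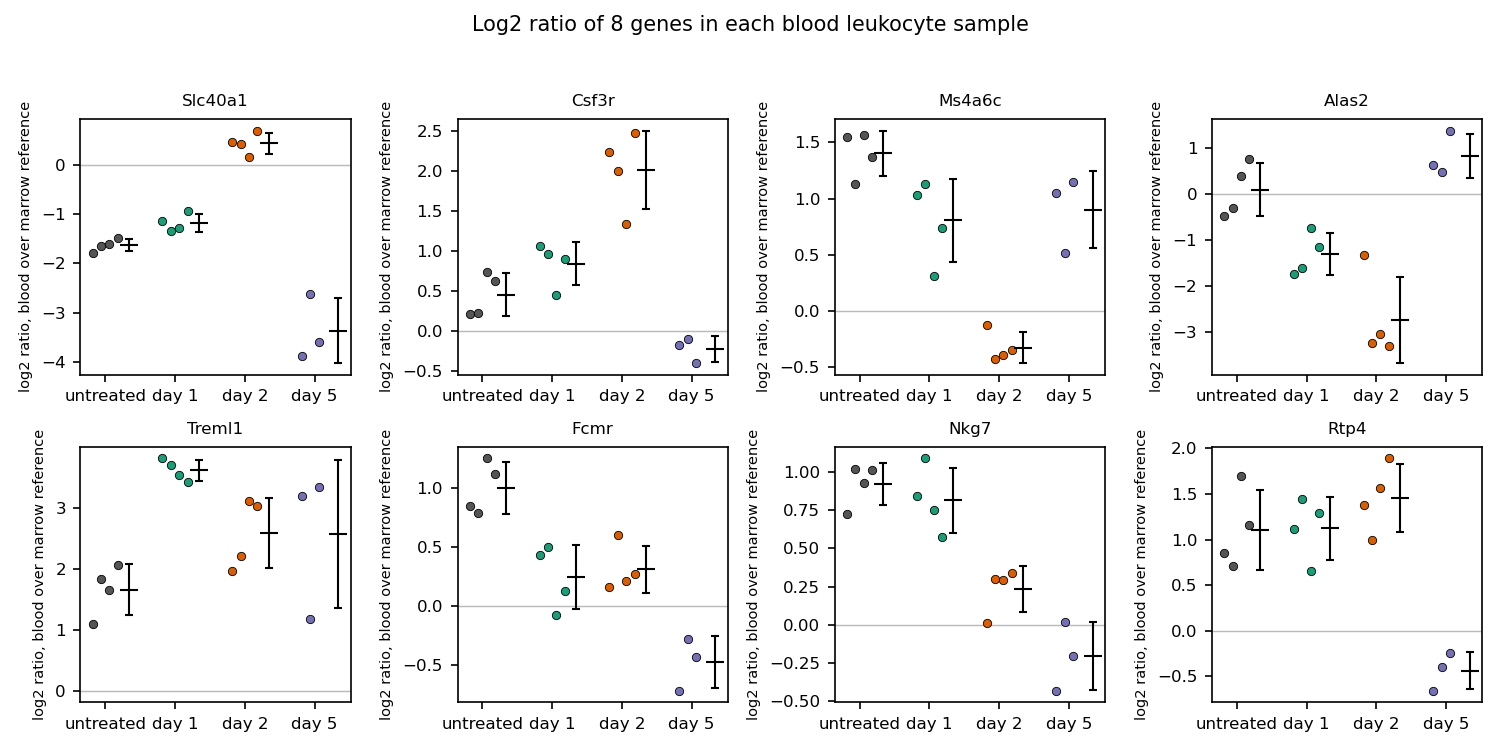
Log2 ratio of blood over reference for 8 genes in each sample, with points for samples and bars for mean and SD per group; the vertical axis is log2. Slc40a1 was -1.64 ± 0.12 in untreated samples, 0.43 ± 0.21 at day 2 and -3.36 ± 0.66 at day 5.

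At day 5 after the drug, a few transcripts of B cells (3 of 11 tested list members), of NK cells (2 of 9) and of the interferon response (2 of 16) were lower than in untreated mice. The calls of these 3 lists did not hold with an estimated correlation (adjusted p = 0.060, 0.12 and 0.34). Ms4a1, the B cell antigen CD20, fell by 1.56 ± 0.24 (SE, adjusted p = 0.0036), from 0.17 ± 0.33 (SD, n = 4) to -1.39 ± 0.56 (SD, n = 3). Fcmr fell by 1.47 ± 0.17 (SE, adjusted p = 5.45e-04), Nkg7 by 1.13 (adjusted p = 8.32e-04), and the interferon-induced genes Rtp4 and Ifi27l2a by 1.54 and 1.23 (adjusted p = 0.0046 and 9.34e-04). Slc40a1, higher at day 2, fell below untreated by 1.73 ± 0.22 (SE, adjusted p = 8.94e-04). Only 71 features changed, 17 higher and 54 lower, while 1134 had an unadjusted p under 0.05.

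The NK and cytotoxic cell list fell at day 5, with 2 of 9 members lower, 3 adjusted over the list alone, 0 positive, and a mean of -0.58 (adjusted p = 1.09e-05). An estimated correlation gave the list an adjusted p = 0.12. Klrd1 was its other called member (-1.08, adjusted p = 0.011). The interferon-stimulated list fell, with 2 of 16 members lower, 5 lower and 1 higher adjusted over the list alone, and a mean of -0.41 (adjusted p = 1.53e-04). The list had an adjusted p = 0.34 with an estimated correlation. The B cell list fell, with 3 of 11 members lower, also 3 adjusted over the list alone, 5 positive, and a mean of -0.41 (adjusted p = 3.21e-04, and 0.060 with an estimated correlation). Its median change was -0.19, so the members did not move as 1. Of its members, Cd22, an inhibitory receptor, fell by 1.18 (adjusted p = 0.011). The immediate early list fell, with 1 of 16 members lower, 4 lower and 1 higher adjusted over the list alone, and a mean of -0.52 (adjusted p = 0.0037). With an estimated correlation the list had an adjusted p = 0.33. Its called member Rgs2 fell by 0.62 (adjusted p = 0.014). The untreated samples themselves were split for this list, with means per sample, relative to their average, of -0.21 and -0.24 in replicates 1 and 2 and 0.26 and 0.20 in replicates 3 and 4. Replicate 3 of day 5, at -0.19, lay above the first 2. The platelet and megakaryocyte list rose, with 1 of 8 members higher, 3 adjusted over the list alone, 7 positive, and a mean of 0.66 (adjusted p = 0.0058, and 0.33 with an estimated correlation). Its means per sample, relative to the untreated average, were 1.05, 0.11 and 1.38 in replicates 1, 2 and 3 of day 5. Replicate 2 thus lay close to the highest untreated mean of 0.039.

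The largest rises at day 5 were in H1f2, a linker histone (1.46 ± 0.27, SE, adjusted p = 0.013), F2rl2 (1.42, adjusted p = 0.048), Clca3a1 (1.25, adjusted p = 0.026), Dut (1.20, adjusted p = 0.0043), Ufsp1, a protease of the UFM1 pathway (1.02 ± 0.11, SE, adjusted p = 4.13e-04), and Rsu1 (0.98, adjusted p = 0.028). Cyp4f18, a leukotriene-oxidising cytochrome P450, fell by 1.504 (adjusted p = 8.32e-04). Gpx4 rose by 0.94 (adjusted p = 0.045), and Cxcr4, a homing receptor measured by 2 probes, and Ebi3, a cytokine subunit, both fell by 0.90 (adjusted p = 0.037 and 0.026). Cdkn1a, Alas2 and Pf4 had changes of -0.49, 0.74 and 0.70 that did not pass (adjusted p = 0.52, 0.39 and 0.62).

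Of 19 named calls at day 5, 9 were kept in every alternative and 10 were lost without replicate 1 of day 5 (H1f2, F2rl2, Clca3a1, Rsu1, Cd22, Klrd1, Rgs2, Gpx4, Cxcr4 and Ebi3). The count was 27, 107 and 224 without replicates 1, 2 and 3 of day 5, and 42 and 40 without untreated replicates 3 and 4. The platelet and megakaryocyte list lost its call without replicate 3 of day 5 (mean 0.43, adjusted p = 0.27) and with a robust trended prior (adjusted p = 0.056), and the immediate early list without replicate 2 of day 5 (adjusted p = 0.075). Quantile normalization gave Rgs2 a change of -0.998, which still passed. With no filter the means were -0.34 for the NK and cytotoxic cell list, 0.41 for the platelet list and -0.27 for the interferon-stimulated list, all still called.

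**Figure D3:**
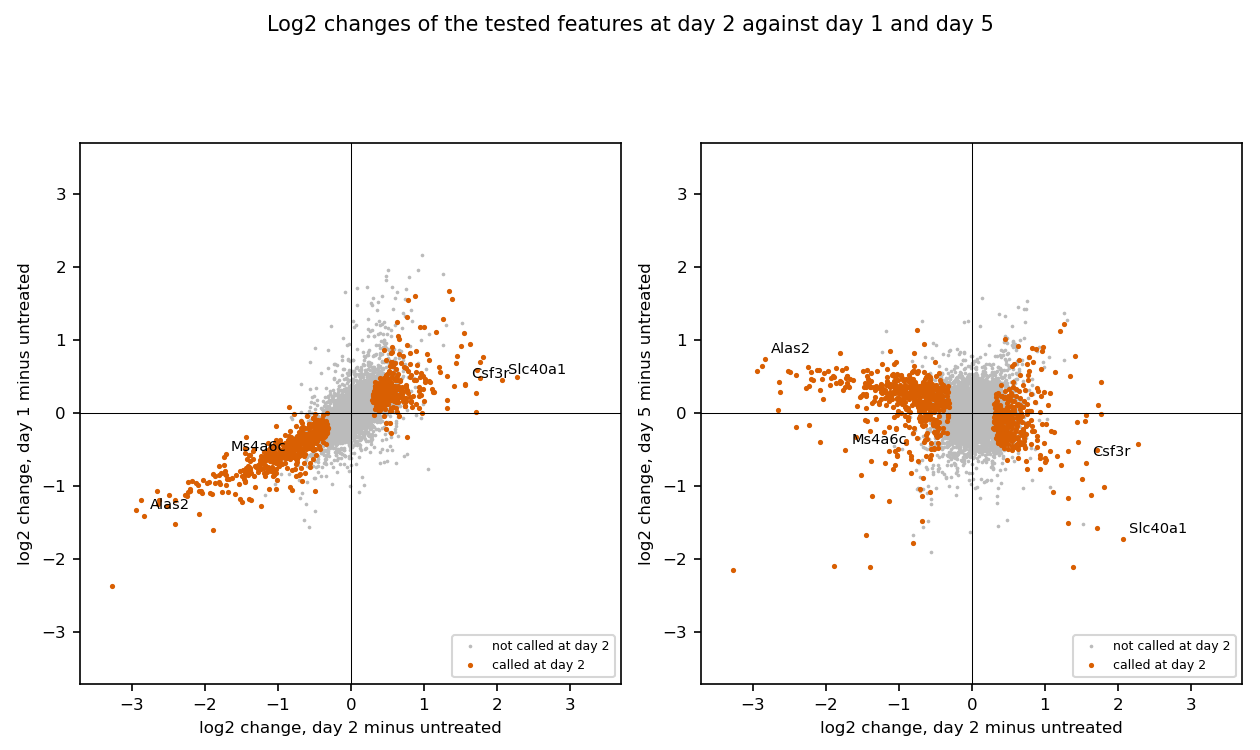
Log2 change of each tested feature at day 2 against its change at day 1 and at day 5; both axes are log2 changes against untreated and orange marks features called at day 2. Across features the changes at day 1 and day 2 correlated with r = 0.730, where groups simulated without any change gave a mean of 0.495 through the shared untreated samples. Those at day 2 and day 5 correlated with r = -0.097, against a mean of 0.462 (range 0.419 to 0.507) in the same simulation, added for these days after the data were seen.

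Between day 1 and day 2, Slc40a1 rose by 1.62 (adjusted p = 0.0034), Cyp4f18 by 1.24 (adjusted p = 0.0061), S100a9 by 1.70 (adjusted p = 0.042) and Myo7b by 1.29 (adjusted p = 0.026). Syt9, Serpina1a, Myf6 and Anxa4, all of the set that moved with Alas2, fell by 1.68, 1.44, 1.39 and 1.37 (adjusted p = 0.021, 0.037, 0.029 and 0.042). The mature neutrophil list rose, with 3 of 12 members higher, 5 adjusted over the list alone, and a mean of 0.69 (adjusted p = 1.65e-08; adjusted p = 4.46e-05 with an estimated correlation), and the monocyte list fell, with 2 of 13 members lower, 4 adjusted over the list alone, and a mean of -0.26 (adjusted p = 0.0053). An estimated correlation gave the list an adjusted p = 0.35. On complete genes its mean was -0.44. In total 75 features changed, 35 higher and 40 lower; the count was 37, 6 and 3 without replicates 1, 3 and 4 of day 1, 7 and 28 without replicates 2 and 4 of day 2, and 41 and 31 without untreated replicates 1 and 3. Only Slc40a1 and Cyp4f18 of the 8 named calls were kept in every alternative.

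From day 1 to day 5, cell division genes were among the largest rises: Sgo1, which protects centromeric cohesion, rose by 2.27, Ube2c, a ubiquitin-conjugating enzyme of mitosis, by 2.24 and Cdca8, a chromosomal passenger protein, by 2.09 (adjusted p = 0.0039, 0.012 and 0.0085). The cell division list had 3 of 19 members higher and 1 lower, 5 and 1 adjusted over the list alone, and was not called (mean 0.73, adjusted p = 0.087). Alas2 rose by 2.14 (adjusted p = 0.0040). Slfn4, a myeloid Schlafen gene, fell by 2.75, Capn3, a calpain, by 2.48, Serpinb6a fell by 2.35 and Dapl1 by 2.32 (adjusted p = 0.0065, 0.024, 0.0020 and 0.0019). Of 1222 changed features, 630 were higher and 592 lower; the count was 749 and 723 without replicates 1 and 2 of day 1, and 718 and 735 without replicates 1 and 2 of day 5. The call of Capn3 was lost without replicate 2 or 4 of day 1 or replicate 1 or 2 of day 5.

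From day 2 to day 5 the mature neutrophil list fell, with 6 of 12 members lower, 7 adjusted over the list alone, and a mean of -1.11 (adjusted p = 5.10e-04). The list had an adjusted p = 0.025 with an estimated correlation. The monocyte list rose, with 6 of 13 members higher, 6 higher and 1 lower adjusted over the list alone, and a mean of 0.41 (adjusted p = 0.035). With an estimated correlation the list had an adjusted p = 0.89. Slc40a1 fell by 3.79 ± 0.22 (SE, adjusted p = 7.82e-08), Slfn4 fell by 3.04, Cyp4f18 by 2.82 and Il1rn by 2.48 (adjusted p = 0.0018, 2.12e-07 and 1.29e-05). Alas2, Syt9, Vav2 and Myf6, of the set defined by this movement, rose by 3.57, 3.51, 3.10 and 3.06 (adjusted p = 3.01e-05, 3.94e-06, 4.65e-05 and 5.83e-06). A total of 1664 features changed, 834 higher and 830 lower. The monocyte list lost its call without replicate 2 of day 2 or replicate 3 of day 5 (adjusted p = 0.067 and 0.11). It also lost it with no filter, technical replicate 2 alone, a robust trended prior, array weights, the replicate block and without the 2 least alike samples (adjusted p = 0.054, 0.065, 0.051, 0.060, 0.062 and 0.058), and its mean was 0.70 on complete genes and 0.67 with technical replicate 1 alone, where it was called.

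Of the features called at day 1 and at day 2, 188 changed in the same direction on both days, 52 higher and 136 lower, and 0 in opposite directions; independent draws would give 7.20 and 11.8. Both comparisons share the untreated samples: in simulations of unchanged groups the changes correlated with a mean r of 0.495 (range 0.452 to 0.543) against 0.730 observed. With separate pairs of untreated samples for each day, where fewer features pass, the median overlap was 4 (0 to 33). The median correlation across genes was then 0.535 (0.374 to 0.641 over 6 splits). Such comparisons share no samples, so the simulated 0.495 does not apply to them. Their median covariance was 0.082 (0.063 to 0.092), against 0.099 with shared untreated samples and a simulated mean of 0.019 (highest 0.023). Shared untreated samples alone therefore do not account for the covariance of day 1 and day 2 changes. Genes are not independent replicates. Of 511 features lower at day 2, 444 moved back by day 5 and 14 were still called lower. Of 315 higher at day 2, 246 moved back, 2 were still called higher and 10 were called lower. Moving back was read from day 5 against day 2, in which 1664 of all 6515 tested features were called. That comparison reuses the day 2 samples by which these features were selected, which favours a move back. The counts are therefore not independent evidence of a return.

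The remaining lists were not called by camera on any day against untreated; its adjusted p values are given for days 1, 2 and 5 in order. T cell (7 tested) had 0.296, 0.960 and 0.347. Neutrophil precursor granule (14) had 0.513, 0.771 and 0.430, and erythroid (19) 0.740, 0.771 and 0.211. Cell division (19) had 0.314, 0.771 and 0.211, and DNA replication (19) 0.949, 0.375 and 0.211. The p53 targets (14) had 0.808, 0.510 and 0.329, and DNA repair and damage signalling (10) 0.694, 0.798 and 0.658. Aldehyde and glutathione detoxification (21) had 0.577, 0.865 and 0.501, and cytokine and chemokine (25) 0.949, 0.885 and 0.449. Regulatory T cell (8) had 0.740, 0.488 and 0.347, MHC class II (5) 0.234, 0.673 and 0.347, and dendritic cell (11) 0.106, 0.134 and 0.640. Adhesion and homing (14) had 0.823, 0.798 and 0.347, apoptosis (14) 0.577, 0.994 and 0.211, and unfolded protein response and heat shock (14) 0.694, 0.798 and 0.501. Endothelial and fibroblast (14) had 0.694, 0.865 and 0.329, ribosomal protein (32) 0.314, 0.689 and 0.347, and oxidative phosphorylation (37) 0.694, 0.967 and 0.508. The fry test, which asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes, called 4 lists on each of the 3 days. It called the dendritic cell list lower at day 2 (adjusted p = 0.0057, 7 complete genes), and did not call B cell at day 1, NK and cytotoxic cell at day 2 or immediate early at day 5 (adjusted p = 0.17, 0.056 and 0.087).

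Some lists had a median, mean and test of different sign on a day on which they were not called. At day 1 these were DNA replication (median 0.03, mean -0.06), p53 targets (0.09 and -0.0031), aldehyde and glutathione detoxification (0.04 and -0.03), cytokine and chemokine (0.10 and -0.03), regulatory T cell (-0.06 and 0.04), adhesion and homing (-0.0067 and 0.10) and immediate early (-0.07 and 0.13). At day 2 they were erythroid (0.07 and -0.05), p53 targets (0.0028 and -0.21), apoptosis (0.09 and -0.05), T cell (-0.02 and -0.05, test higher), aldehyde and glutathione detoxification (0.08 and 0.0032, test lower) and oxidative phosphorylation (0.02 and 0.02, test lower). Called lists on other days had these adjusted p values: NK and cytotoxic cell 0.577 at day 1, mature neutrophil 0.545 and 0.347 at days 1 and 5, monocyte 0.347 at day 5, interferon-stimulated 0.823 and 0.798 at days 1 and 2, platelet and megakaryocyte 0.195 at day 2, stem and progenitor cell 0.567 and 0.651 at days 2 and 5, B cell 0.195 at day 2, immediate early 0.740 and 0.771 at days 1 and 2, and eosinophil, basophil and mast cell 0.329 at day 5. An exact two-sided permutation test of the list means per sample, chosen after the data were seen, gave the smallest possible p of 0.0286 for the called lists against untreated except monocyte at day 1, NK and cytotoxic cell at day 2 and interferon-stimulated at day 5 (0.0571 each) and immediate early at day 5 (0.171).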

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

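The tests of neutrophil precursors, of the lymphocyte share and of genes of other tissues, the set that moved with Alas2 and the joined red cell list were chosen only after the result was seen.

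A set of 102 features, 70 with a gene symbol, fell at day 2 and rose again by day 5 together with Alas2. Within groups its members correlated with a mean r of 0.564, against at most 0.039 in 1000 random sets. The random sets were drawn from all features with complete values, not matched to the set in direction or size of change. The contrast therefore does not show that the set differs from other features that move alike. Fewer young red cells at day 2 could account for Alas2, but a second list of reticulocyte genes had a median change of -0.12. Its 95% bootstrap interval over genes was -0.26 to 0.37. These values meet the bound written beforehand against that explanation, but only 6 of the list's 43 genes were measured. Joined with the erythroid list, which holds the called Alas2 and Bnip3l, the median over 25 genes was -0.06 (-0.26 to 0.25). Both intervals resample genes and not samples, so they do not give the spread between samples. Pairs of set members from the same plate of the probe numbering, summed over 36 plates, numbered 165 against a random 95th percentile of 184. The set was thus not concentrated on plates beyond random draws. Positions of wells within a plate were not used, so neighbouring wells are not excluded. The tables argue against the scale of the columns, since 99.02% of the set was still called lower after quantile normalization. Genes of other tissues were 3.06 times as frequent in the set as among other named genes (14.3% and 4.66%, one-sided Fisher's exact p = 0.00168), but those families were written down after the set had been seen, so 1 shared RNA binding to many probes stays open and cannot be told apart from joint regulation. A biological explanation by day after treatment stays open as well.

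Of the mature neutrophil list 6 of 12 members were higher and of the monocyte list 7 of 13 lower at day 2, but 3 monocyte members had positive changes and that list's call was lost (adjusted p = 0.12 with an estimated correlation). A release of precursors from the marrow may raise neutrophil genes. The precursor list, however, had a mean change of -0.13 (bootstrap interval over its genes -0.57 to 0.30), against 0.92 for the mature list. Its 14 tested members were mixed: 1 was called higher (Chil1) and 2 lower (Ctsc and Plac8), and 6 had positive changes. Ctsc, which fell by 2.07, belongs to the set that moved with Alas2. The mean therefore does not show a joint fall of precursor genes, and its interval does not give the spread between samples. A lower share of lymphocytes alone would raise both lists, whereas the monocyte list fell. The 2 means over all tested members with a value in the sample differed by at least 1.28 in each day 2 sample. Over complete genes the lowest neutrophil mean was 0.86 and the highest monocyte mean -0.81. That gap restates the pattern itself, so it is not a separate test of this explanation. The scale of the columns is argued against by the higher adjusted p of the pair after quantile normalization, 4.81e-05. A hypothesis that stays open is a changed ratio of circulating neutrophils to monocytes after the drug; no cell counts were used here.

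Of the platelet list 4 of 8 members were higher at day 1, and the list's call was lost (adjusted p = 0.060 with an estimated correlation). More platelet RNA in the preparations is a candidate explanation. A second platelet list had a median change of 0.79 over 9 genes without Ppbp, which the first list also holds (bootstrap interval over genes -0.04 to 1.19). Over 10 genes with Ppbp it was 0.70 (0.0084 to 1.12). Both medians lie above the 0.5 written beforehand, but the intervals reach below it and do not give the spread between samples. The scale of the columns stays open too, since quantile normalization ended the call (adjusted p = 0.073, the highest of its alternatives, whose lowest was 1.05e-12). The list mean was 2.01 ± 0.038 (SD) in untreated and 3.24 ± 0.061 in day 1 samples as deposited, and 2.32 ± 0.35 and 2.82 ± 0.11 after it. These genes lie at a median percentile of 99.7 of the untreated columns, where that normalization gives all columns the same values, so a true rise would shrink as well.

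At day 1, day 2 and day 5 against untreated, only the real 1 of 35 splits into groups of the same sizes gave as many changed features. The real counts were 300, 826 and 71, and the highest others were 1, 1 and 3. The same held for day 2 against day 1 (75, highest other 3), day 5 against day 1 (1222, 629) and day 5 against day 2 (1664, 579). A share of 1 of 35 is the smallest that these splits can give. Mixed groups also carry the group difference in their spread, which leaves few calls in most, so the splits alone do not exclude chance. In the F test 1 of 100 draws of the labels gave as many (1476, highest other 51). For the overlap of day 1 and day 2 calls it was also 1 of 100 draws (188, 2), but shuffled labels leave almost no calls on either day, so this does not show an overlap beyond what the shared untreated samples bring. For the number of lists called, chance is not excluded: 14, 15 and 13 of 35 splits gave as many as the real 5, 4 and 5, and the highest others were 14, 11 and 11. Other splits that call more lists than the real one point to a structure of the samples shared by genes of a list. Untreated replicates 1 and 2 differed from 3 and 4 in this way: relative to the untreated average their means were -0.48, -0.53, 0.44 and 0.57 for the T cell list, 0.32, 0.56, -0.37 and -0.51 for cell division, and -0.10, -0.34, 0.21 and 0.24 for the interferon-stimulated list. At day 2 the T cell means of replicates 1 to 4 were -0.77, -0.33, 0.05 and 0.86 and those of cell division 0.65, 0.38, -0.11 and -0.20, a split by the same numbers, whereas at day 1 they were 0.39, 0.63, -0.01 and 0.37, and -0.16, -0.50, -0.03 and -0.33. At day 5 the T cell means of replicates 1 to 3 were -0.48, -0.93 and 0.17, split in the same way. Those of cell division were 0.09, 0.50 and 0.34, which were not. The cause was not tested. In simulations with independent genes, by contrast, 0 of 260 unchanged lists were called.

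In 16 of 253 groups of 4 values, 1 sample lay far from the other 3 by Dixon's criterion, where chance gives about 5%. In untreated replicate 2, Irf9 was -0.26 against 0.07 to 0.13 in the others. At day 1, Pf4 was 4.43 in replicate 1 (others 3.74 to 3.81), Kdr was -0.23 in replicate 3 (0.65 to 0.78), and in replicate 2 Cxcr4 was 0.63 (0.27 to 0.31) and Sgo1 -3.05 (-2.79 to -2.76). At day 2, replicate 3 had Ereg at 2.49 (0.43 to 0.69), Serpinb6a at 1.99 (0.41 to 0.62), Adgre1 at -0.40 (-0.12 to -0.10), Il4 at -0.68 (-0.17 to -0.07) and Cd72 at -2.09 (-1.11 to -0.998). Replicate 1 of day 2 had Clu at 2.82 (4.33 to 4.59), Alas2 at -1.33 (-3.30 to -3.05), Nkg7 at 0.012 (0.30 to 0.34) and H1f2 at 2.28 (3.33 to 3.37). Mpeg1 was 0.15 in replicate 4 of day 2 (-0.15 to -0.12), and Slfn4 was -0.35 in replicate 2 of day 2 (2.43 to 2.80). Called against untreated at both day 2 and day 5 in opposite directions, and also called in the test of day 5 against day 2, were 13 features, among them Slc40a1, Cyp4f18, Rgs2, Jdp2, Atp11b, Hspb2, St3gal6 and Ublcp1. Outside the tested features, 12 had a value in all day 5 samples and in 0 untreated samples, and 2 the reverse.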

How the results depend on the processing

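The tests without the 2 samples whose technical replicates were least alike and without the set that moved with Alas2 were chosen only after the result was seen. None of 127 named gene results and 18 list results changed direction in any alternative that was run. The 18 list results were those called against untreated and, between days, calls of the mature neutrophil and monocyte lists only. The lists and most of the genes were taken because they were called, and each alternative reuses the same samples. A change of direction was therefore unlikely from the start. Named gene results lost their call 145 times in alternatives and 258 times with 1 sample left out, and list results 42 and 15 times. Signal over background is not given in the sources used here, so its limit on weak features is unknown. Across features, samples with the same replicate number showed no pairing: 7 of 21 such pairs had r over 0.1, and 4 of 15 samples were closest to their own number. This check does not ask about a split between sets of replicate numbers, as some lists showed in untreated and day 2 samples.

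Counts that moved by over 1.5 times are given by setting; where the construction does not show it, the cause was not tested. Quantile normalization gave 462 features at day 1 (258 shared) and 111 at day 5 (61 shared). Genes complete in all samples, fewer genes by construction, gave 3 lists at day 1. They gave 116 features at day 5, a rise whose cause was not tested. No filter gave 162 at day 1 and 25 for day 2 against day 1. Technical replicate 1 alone gave 3 lists at day 1 and 44 features for day 2 against day 1, and replicate 2 alone 3 lists at day 1 and 2 at day 2. The sample as a random effect gave 715 at day 1, 407 at day 5, 274 for day 2 against day 1, and 2 lists at day 2. Array weights gave 864 at day 1. Fits of 2 groups, with fewer samples, gave 578 at day 1, a rise whose cause was not tested, and 3 lists. They gave 34 at day 5, 5 for day 2 against day 1 and 935 for day 5 against day 2. The replicate block gave 107 at day 1 and 33 for day 2 against day 1. A 2-fold minimum, which removes smaller changes by construction, gave 75, 204 and 32 at days 1, 2 and 5, 37 for day 2 against day 1, 207 for day 5 against day 1 and 359 for day 5 against day 2. An estimated correlation gave 0, 1 and 0 lists at days 1, 2 and 5. Without the least alike samples 46 were called at day 5 and 6 for day 2 against day 1, and without the set that moved with Alas2, 192 at day 1 and 25 for day 2 against day 1. Separate untreated samples for each day gave an overlap of 4.

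With each sample left out in turn, day 1 counts ran from 60 (without replicate 2 of day 1) to 438 (replicate 3), with 3 to 7 lists; day 2 counts from 529 (untreated replicate 4) to 942, with 2 to 5 lists; and day 5 counts from 27 (replicate 1 of day 5) to 224 (replicate 3), with 4 to 8 lists. Counts ran from 3 to 94 for day 2 against day 1, 718 to 1571 for day 5 against day 1, 1196 to 1856 for day 5 against day 2, and 1111 to 1673 in the F test.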

Other observations

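Lists not described above also moved between days. From day 1 to day 2 the platelet and megakaryocyte list fell (mean -0.67 over 8 members, 0 called and 4 lower adjusted over the list alone, adjusted p = 0.0053; adjusted p = 0.31 with an estimated correlation), and so did the NK and cytotoxic cell list (-0.28 over 9, 1 lower and 2 adjusted over the list alone, adjusted p = 0.0053; adjusted p = 0.35 with an estimated correlation). The p53 target list fell (-0.21 over 14, 0 called and 3 lower adjusted over the list alone, adjusted p = 0.042; adjusted p = 0.076 with an estimated correlation). The cell division list rose (0.44 over 19, 0 called, 0 adjusted over the list alone, adjusted p = 0.0063; adjusted p = 0.55 with an estimated correlation), as did the ribosomal protein list (0.26 over 32, 0 called, 0 adjusted over the list alone, adjusted p = 0.0053; adjusted p = 0.076 with an estimated correlation).

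From day 2 to day 5 the eosinophil, basophil and mast cell list rose (0.49 over 8 members, 5 higher and 5 adjusted over the list alone, adjusted p = 0.035; adjusted p = 0.11 with an estimated correlation), and the interferon-stimulated list fell (-0.45 over 16, 5 lower and 1 higher, also 5 and 1 adjusted over the list alone, adjusted p = 0.035; adjusted p = 0.94 with an estimated correlation). From day 1 to day 5 the eosinophil, basophil and mast cell list rose (0.41 over 8, 5 higher and 5 adjusted over the list alone, adjusted p = 0.040; adjusted p = 0.20 with an estimated correlation). Falls over the same interval were called for the NK and cytotoxic cell list (-0.44 over 9, 3 lower and 3 adjusted over the list alone, adjusted p = 0.040), the interferon-stimulated list (-0.44 over 16, 3 lower and 3 adjusted over the list alone, adjusted p = 0.029) and the immediate early list (-0.65 over 16, 4 lower and 1 higher, 5 and 1 adjusted over the list alone, adjusted p = 0.040). These 3 had an adjusted p = 0.47 with an estimated correlation. These comparisons between days share samples with those against untreated, so the lists are not independent evidence. Apart from the estimated correlation and fry, the alternatives and the leaving out of single samples were not examined for the lists of this section. The fry test called 2 lists from day 1 to day 2, mature neutrophil and monocyte, and 10 and 8 lists from day 1 and day 2 to day 5. The tests were those fixed before the data were examined, extended to comparisons between days after the result was seen.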
